A study of Mus musculus with 42 samples.

How the data were processed

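RNA from B cells, T cells and the remaining cells (named non-BT cells in the labels) of mouse spleen was sequenced from animals labelled Psmb8 +/+ (wild type) or Psmb8 G201V/G201V (homozygous), in an Old and a Young age group. Ages in weeks, the strain, the sex of the animals and the way the cells were separated are not stated in the labels. Per the labels' protocols, total RNA was taken with a micro-scale column kit (RNeasy micro), full-length cDNA was made with the SMART-Seq HT kit, which amplifies polyadenylated RNA by PCR, and libraries were made with the Nextera XT transposase kit. Neither kit marks the strand, and no molecular identifiers are named, so reads of a gene and of a gene on the opposite strand cannot be told apart and copies made by PCR cannot be removed.

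Each deposited file holds FPKM (fragments mapped to a gene, scaled by transcript length and by the number of mapped fragments of the library) for 1 library, calculated by the authors from the mapped reads, per the file headers. Per the submitters' processing notes, HISAT2 2.1.0, Cufflinks 2.2.1 and Cuffdiff (version not stated) were used with genome build GRCm38.p4. The annotation release, the read filters and the number of reads are not stated. Every file lists the same 47719 Ensembl gene identifiers. Of these, 47305 were matched by identifier to a symbol and coordinates in GENCODE M21 on GRCm38, and 21276 were at 0 in every library. FPKM is a share of the library, so a gene family that takes many reads lowers the values of all others. How the authors' counting divided reads between near-identical genes, such as the kallikreins, the H2-Q genes, the histone genes, the haemoglobins and the immunoglobulin segments, is not stated, and values of such genes are uncertain in how they divide within the family.

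Counts were not among the files used here. The number of fragments behind each library was therefore estimated from the smallest step of FPKM times length over 5684 genes with a single transcript of at least 1500 bases. The estimates ran from 9480000 to 25730000 fragments with a median of 18650000, and the ratio of low values within a gene between libraries was 0.995 to 1.018 times the ratio of the estimates. At these depths a value of 1 FPKM for a transcript of 2 kb stands for about 19.0 fragments in the library with the fewest and 51.5 in the library with the most. A shorter transcript stands for fewer fragments at the same FPKM, which applies to the small RNA genes Snord13 and Rny3 named below. No counting intervals were calculated from these estimates.

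The values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend). Genes with at least 1 FPKM in at least 3 of the 14 libraries of a cell type were tested, which were 12269 genes in B cells, 13193 in T cells and 13587 in non-BT cells. The 4 groups of a cell type (old and young, wild type and homozygous) were fitted together so that they shared 1 estimate of the spread per gene. The contrasts were homozygous minus wild type in old animals (3 against 3), the same in young animals (4 against 4), the mean of both, their difference (the age by genotype interaction), and old minus young in wild-type animals. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested in the cell type and a threshold of 0.05. Differences of the averaged genotype effect between cell types were tested over all 42 libraries with the animal label as a block (duplicateCorrelation in limma, correlation 0.0771) and 15143 genes.

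A set of 45 gene lists was fixed before the data were examined, as were the tests, the threshold, the filter and the rule for named genes. The lists cover interferon responses, the proteasome, antigen presentation, protein folding and stress responses, inflammation, metabolism, the cell cycle, and markers of the cell types that spleen preparations can hold, and together they hold 717 genes. Lists with at least 3 members past the filter were tested with camera in limma, with a preset correlation between genes of 0.01 and adjustment over the lists of a contrast. An estimated correlation in camera and fry were alternatives. Members were also counted after adjustment over the list alone. A score per library was the mean of log2(FPKM + 1) over the members, and groups were compared by a two-sided exact permutation test of the difference of means. With 3 against 3 libraries the smallest p this test can give is 0.1, and with 4 against 4, or 3 against 4, it is 0.0286. An exact test over both ages, with labels exchanged within each age, can reach 0.00143. That test, the test of the immunoglobulin share and a paired form of the list test between cell types were added after the data had been seen.

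Psmb8 is given first. Then, for each age and cell type, the 10 largest rises and the 10 largest falls were named among genes past the threshold whose homozygous libraries all lay above or all lay below every wild-type library, without immunoglobulin and T cell receptor segments, predicted genes, pseudogenes, and olfactory and microRNA genes. Members of the lists that passed were added, up to 4 per list. Where fewer than 5 genes passed, the 10 with the smallest p are given as values. For the other contrasts the 5 largest rises and 5 largest falls were named. The text names a part of the genes this rule gives where they are many. The results of 3 single genes are not reported here.

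Genotypes were assigned by library title. In 3 young libraries titled wild type, all replicate 4, the genotype label reads Psmb9 +/+ in place of Psmb8 +/+. They were kept as wild type, and the counts, the list tests and the named genes were repeated without them. Titles give the 3 cell types of an animal the same age, number and genotype, so the 42 libraries stand for 14 animals by title. The labels do not otherwise state that libraries of a group come from separate animals, and the p-values measure the spread between these libraries. Wild-type and homozygous animals share replicate numbers. Libraries with the same number were taken as paired where every pair's residuals (deviations from the group mean, over genes) correlated above 0.1, which held for old B cells (0.190, 0.287 and 0.194 for numbers 1, 2 and 3) and for no other comparison. What a number marks is not stated.

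Library names fall into 3 ranges of numbers, which hold 12, 18 and 12 libraries. Each range holds equal numbers of wild-type and homozygous libraries of each cell type, but the ranges follow age in part, so the range was fitted as a covariate in an alternative. The other alternatives were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 FPKM, quantile normalization, median-of-ratios scaling, array quality weights, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Leaving out the old animals numbered 2 was added after the data had been seen.

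The tests were checked on simulated values made from the real means and spreads, with 200 genes changed by known amounts. In the comparison of young non-BT cells, 17.9% of genes changed by 0.5 on the log2 scale, 70.1% of those changed by 1 and 89.4% of those changed by 2 were recovered, with 5 false calls. In that of old T cells the shares were 5.97%, 53.7% and 87.9%, with 1 false call. When the 20S proteasome list was raised by 0.3 in the simulated young comparisons, camera called it in each cell type and called no other list. The simulated genes varied independently of each other. The simulation therefore does not show how often camera calls lists falsely where genes are correlated, as in the real data. Tables and plots were made with Python 3.11.15 and the packages pandas 2.3.3 and matplotlib 3.10.9.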

Results

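Gene expression was measured in B cells, T cells and non-BT cells (the remaining cells) from the spleens of mice homozygous for a G201V change in Psmb8 and of wild-type mice. Psmb8 encodes the β5i subunit of the immunoproteasome, the form of the proteasome that cells of the immune system carry and that makes peptides for presentation on MHC class I. The series title ties the variant to a human proteasome-associated autoinflammatory syndrome, and the stated purpose was to find genes whose expression differed between the genotypes in each of the 3 cell types. The 42 libraries fell into 12 groups. Each cell type had 3 old wild-type, 3 old homozygous, 4 young wild-type and 4 young homozygous libraries, and none of the animals was treated. The estimated depth was 9480000 to 25730000 fragments per library, with the fewest in old non-BT cells (9480000 to 18290000). Between 10905 and 12696 genes per library reached 1 FPKM. Replicates of a group correlated across genes at Pearson's r of 0.9715 to 0.9901 on the log2 scale. Marker genes set the preparations apart. The mean log2 level of B cell markers in young wild-type libraries was 8.98 in B cells, 3.31 in T cells and 3.84 in non-BT cells, and that of T cell markers was 2.65, 8.28 and 4.28.

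Psmb8 (ENSMUSG00000024338) lies on chromosome 17 at 34197721 to 34201454 of GRCm38, on the plus strand. A single amino acid change leaves reads of the gene in place, so its level does not check the genotype labels. In young animals Psmb8 stood at 672 ± 32.5 FPKM (SD, n = 4) in wild-type and 617 ± 35.5 FPKM in homozygous B cells. The young levels were 764 ± 78.2 and 741 ± 54.8 FPKM in T cells and 589 ± 60.2 and 624 ± 69.5 FPKM in non-BT cells. In old animals (n = 3) it stood at 791 ± 61.2 and 807 ± 142 FPKM in B cells, at 803 ± 36.7 and 836 ± 115 FPKM in T cells, and at 588 ± 22.2 and 715 ± 149.9 FPKM in non-BT cells. No genotype comparison of Psmb8 passed the threshold. Its log2 fold changes ran from -0.12 ± 0.10 (SE) in young B cells to 0.26 ± 0.14 in old non-BT cells, with limma adjusted p of 0.767 and 0.921. The immunoproteasome subunits, their activator and the assembly chaperone gene Pomp formed a list of 6 genes. Its mean log2 level was 8.29 ± 0.13 in wild-type and 8.35 ± 0.17 in homozygous young non-BT cells (n = 4 each, exact permutation p = 0.657). The list was not called in young B, T or non-BT cells (camera adjusted p of 0.682, 0.393 and 0.220). In old animals camera called it as higher in homozygous B, T and non-BT cells, with medians of 0.16, 0.094 and 0.15 (adjusted p of 0.00501, 0.0324 and 0.0383). These calls were lost with an estimated correlation (adjusted p of 0.465, 0.697 and 0.901) and without homozygous replicate 2 (adjusted p of 0.209, 0.410 and 0.633). They were lost as well in B cells without wild-type replicate 1 (adjusted p = 0.0532), in T cells without wild-type replicate 1, 2 or 3 (0.0521, 0.0779 and 0.0766) and in non-BT cells without wild-type replicate 2 (0.257).

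The largest number of differences between genotypes was found in young non-BT cells. Of 13587 genes, 229 passed (limma), 31 higher and 198 lower in homozygous animals (47 and 139 of 186 with quantile normalization). Markers of plasmacytoid dendritic cells, which secrete type I interferon when they sense viral nucleic acid, fell together. Of 12 measured members 11 passed over all genes and 12 passed adjusted over the list alone, with a median log2 fold change of -1.80. Klk1, a kallikrein, fell from 49.9 ± 3.08 to 2.85 ± 1.44 FPKM (SD, n = 4 each). Ly6d fell by 2.79 ± 0.33 on the log2 scale, Cox6a2 by -2.87 ± 0.39, and the receptors Ccr9 and Siglech fell by 2.42 ± 0.38 and 2.08 ± 0.32. Pacsin1 fell from 9.30 ± 0.849 to 1.43 ± 0.402 FPKM, Smim5 by -1.45 ± 0.13 and Cd300c by -1.51 ± 0.32. Tcf4, which encodes the transcription factor that maintains the identity of these cells, fell from 55.5 ± 1.70 to 28.4 ± 4.11 FPKM. The adjusted p of the 11 members ran from 0.000432 to 0.047, and Runx2 (-0.66 ± 0.21, adjusted p = 0.161) did not pass. The mean log2 level of the list was 6.11 ± 0.03 in wild-type and 4.28 ± 0.19 in homozygous libraries (n = 4 each, exact permutation p = 0.0286, the smallest this test can give, 0.0714 after adjustment over the lists). Camera gave an adjusted p of 2.28e-21 for the list, and the call was lost with an estimated correlation (adjusted p = 0.153).

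**Figure D1:**
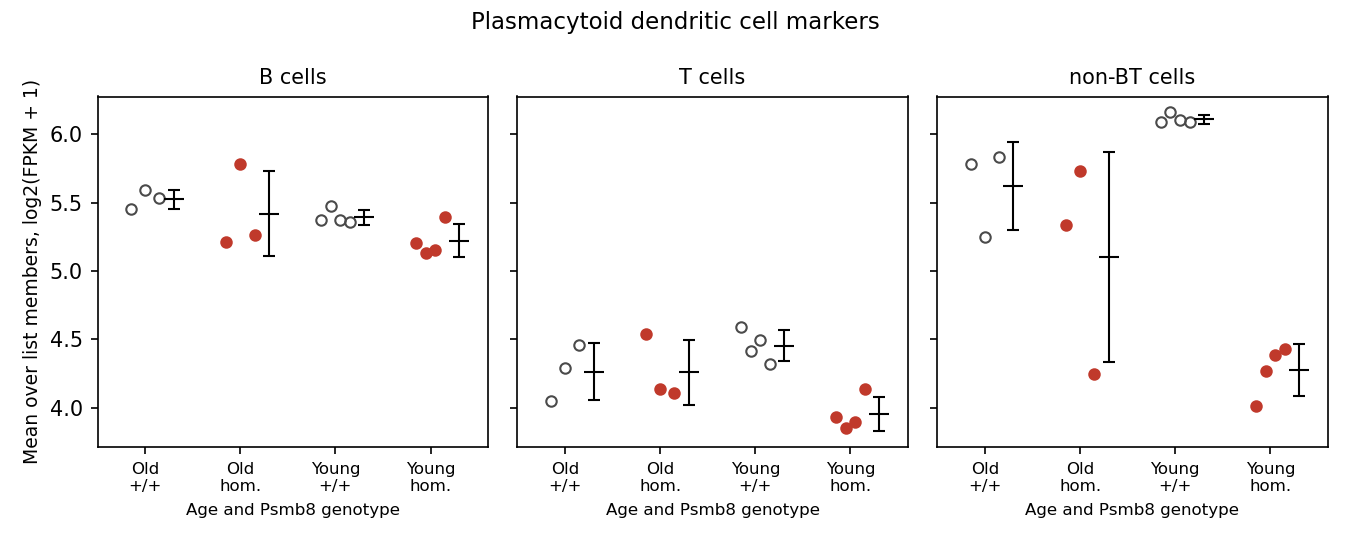
Mean log2(FPKM + 1) over the plasmacytoid dendritic cell markers (vertical axis) in each library of B cells, T cells and non-BT cells, by age and genotype, with open grey points for wild-type and filled red points for homozygous libraries and black bars for the mean ± SD. In young non-BT cells the group means were 6.11 in wild-type and 4.28 in homozygous libraries.

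Other antigen-presenting and lymphoid genes were lower in the same young non-BT libraries. All 18 conventional dendritic cell markers were negative and 4 passed (7 adjusted over the list alone), with a median of -0.43. These were Ccr7, the homing receptor of migrating dendritic cells (-1.47 ± 0.27), Fscn1, which bundles actin in their extensions (-1.36 ± 0.25), the transcription factor gene Irf8 (-0.55 ± 0.13) and Esam (-0.99 ± 0.22). Irf8 is a member of the plasmacytoid list as well. Camera called the list (adjusted p = 3.04e-08), and the call was lost with an estimated correlation (adjusted p = 0.250). Of the MHC class II genes H2-Oa (-1.33 ± 0.26) and H2-Ob (-0.89 ± 0.19) fell, and the list had a median of -0.30 (camera adjusted p = 0.000585, and adjusted p = 0.579 with an estimated correlation). H2-M2 fell by 2.61 ± 0.31, and the sodium channel gene Scn3a fell from 7.41 ± 1.48 to 0.441 ± 0.527 FPKM. Both are outside the lists. Genes of plasma cells, the secretors of antibody, fell as well. Jchain fell from 687 ± 267 to 157 ± 40.9 FPKM, Mzb1 by -2.49 ± 0.50 and Derl3 by -2.37 ± 0.43. In all, 3 of 14 members passed and 7 passed adjusted over the list alone (camera adjusted p = 4.27e-07, and adjusted p = 0.326 with an estimated correlation). Immunoglobulin genes, 26 of which were among the 229, held 6.13 ± 2.34% of summed FPKM in wild-type and 1.17 ± 0.174% in homozygous libraries (n = 4 each, exact permutation p = 0.0286). Of 16 B cell markers Ighm, Spib and Blnk fell (median -0.53, camera adjusted p = 1.97e-05, and adjusted p = 0.250 with an estimated correlation).

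T cell and neutrophil genes in young non-BT cells gave a mixed picture. Cd8b1, the β chain of CD8, fell from 35.1 ± 3.32 to 3.47 ± 0.810 FPKM (n = 4 each), and Il7r fell by 1.45 ± 0.24. None of 19 general T cell markers passed, however (median -0.42, camera adjusted p = 0.0130, and adjusted p = 0.727 with an estimated correlation). The neutrophil receptor genes Csf3r and Cxcr2 fell by 1.21 ± 0.21 and 1.42 ± 0.30 and the cytokine gene Il1b fell from 496 ± 83.1 to 195 ± 63.4 FPKM. The score of the neutrophil list was nevertheless 0.46 higher in homozygous libraries, though it overlapped between the genotypes (exact permutation p = 0.314). The score of 16 monocyte markers was 6.93 ± 0.14 in wild-type and 7.32 ± 0.05 in homozygous libraries (n = 4 each, exact permutation p = 0.0286, 0.0714 after adjustment, camera adjusted p = 0.000206, and adjusted p = 0.326 with an estimated correlation). Among single genes that rose were the coagulation factor gene F10 (1.07 ± 0.22), Gbp3 (0.81 ± 0.19), Tnfsf13, which encodes the B cell survival factor APRIL (0.75 ± 0.17), and Ripk3, a kinase of necroptosis (0.53 ± 0.12). Hist2h2bb rose from 1.57 ± 0.723 to 5.87 ± 0.683 FPKM, Capg by 0.66 ± 0.15 and Sgce by 0.86 ± 0.19. The type I interferon list was not called. Its mean log2 level was 5.31 ± 0.05 in wild-type and 5.28 ± 0.23 in homozygous libraries (exact permutation p = 0.8). Its median fold change was 0.04 and its mean -0.04. The 2 of 50 members that passed, Ly6a (-2.21 ± 0.46) and Bst2 (-0.85 ± 0.19), both fell. Bst2 is a member of the plasmacytoid list as well.

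Genes of the 19S particle and the 20S core of the proteasome rose in young homozygous non-BT cells. Of the 21 genes of the 19S regulatory particle, which feeds substrates into the proteasome core, 6 passed over all genes and 18 adjusted over the list alone. Among them Psmc2 rose from 66.6 ± 2.55 to 97.3 ± 5.82 FPKM, Psmc5 by 0.42 ± 0.09, Psmd13 by 0.36 ± 0.08 and Adrm1 by 0.42 ± 0.09. All 14 genes of the 20S core had a positive fold change, with Psma7 (0.39 ± 0.09) past the threshold over all genes and 12 adjusted over the list alone. Pomp, the chaperone of 20S assembly and a member of the immunoproteasome list, rose from 361 ± 26.1 to 482 ± 29.3 FPKM (n = 4 each). The medians were 0.36 for the 19S and 0.32 for the 20S genes, with camera adjusted p of 3.48e-17 and 9.43e-12. Both calls were lost with an estimated correlation (adjusted p = 0.153 and adjusted p = 0.250). Prdx1, a peroxiredoxin (388 ± 37.5 to 563 ± 60.2 FPKM), the glycolytic enzyme gene Eno1 (0.42 ± 0.09) and the transfer RNA synthetase gene Gars (0.37 ± 0.08) also rose, while Chac1 of the integrated stress response fell by 1.54 ± 0.27. All 32 cell cycle genes were positive without any of them passing (median 0.38, camera adjusted p = 4.90e-07, and adjusted p = 0.579 with an estimated correlation). The count of 229 fell to 60 without homozygous replicate 3 and to 137 without homozygous replicate 1, with the other 6 young libraries in between, and it was 68 without the Psmb9-labelled libraries. It rose to 635 without the old animals numbered 2, to 705 with only the young groups fitted and to 756 with array quality weights, and fell to 104 without the filter.

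**Figure D2:**
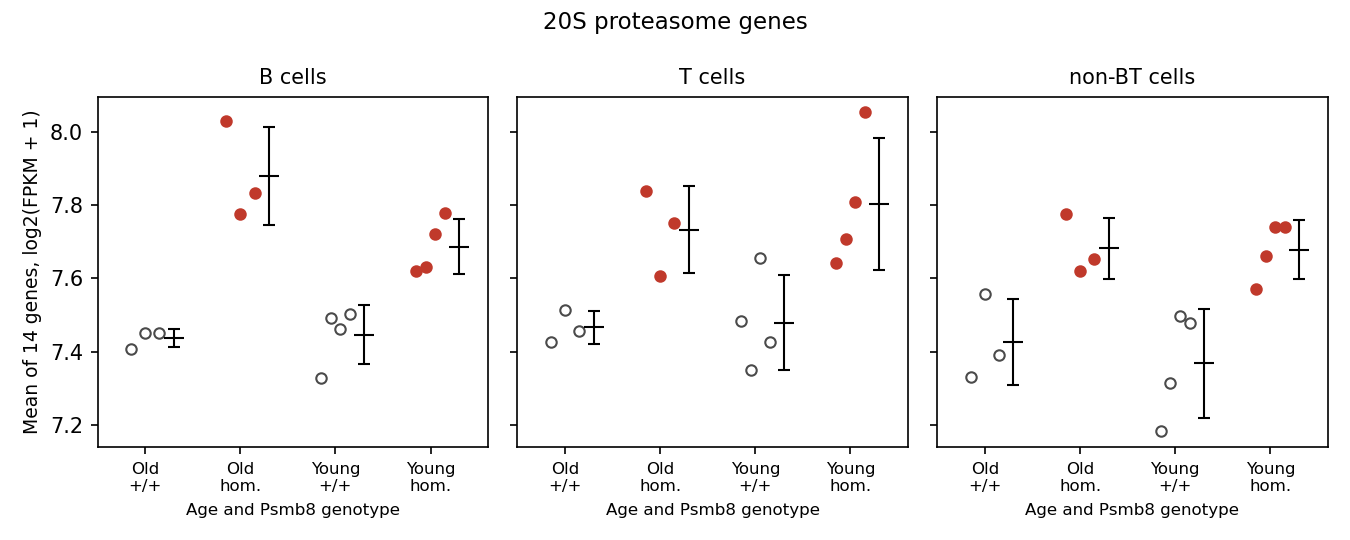
Mean log2(FPKM + 1) over the 14 genes of the 20S proteasome core (vertical axis) in each library, by cell type, age and genotype, with open grey points for wild-type and filled red points for homozygous libraries and black bars for the mean ± SD. Every homozygous mean lay above the wild-type mean of its age and cell type, from 7.69 against 7.45 in young B cells to 7.88 against 7.44 in old B cells.

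In old non-BT cells no gene of 13587 passed (limma, 0 calls with 785 genes at an unadjusted p under 0.05), and 7.47% of genes had genotypes without overlap where chance gives 10%. Values of genes with the smallest p are given without a call. Ctsf, a lysosomal protease gene, stood at 3.21 ± 0.520 FPKM in wild-type and 0.750 ± 0.129 FPKM in homozygous libraries (n = 3 each, limma adjusted p = 0.067). Scn3a had a log2 fold change of -1.81 ± 0.29 (adjusted p = 0.142), Laptm4b of -1.17 ± 0.20, Bglap3 of -1.05 ± 0.18 and Psmd2, a 19S subunit, of 0.45 ± 0.09 (adjusted p = 0.317). Crygn was listed at 0 FPKM in every wild-type library and at 3.05 ± 1.21 FPKM in the homozygous libraries, and Rny3 at 30.1 ± 9.49 FPKM and 0 FPKM. The 19S and 20S lists had medians of 0.25 and 0.26 (camera adjusted p = 6.32e-12 and 2.16e-10). The interferon-gamma list, with Gbp3, Gbp7 and Irgm1 past the threshold adjusted over the list alone, had one of 0.35 (adjusted p = 6.77e-08). The plasmacytoid list had a median of -0.53 with all 12 members negative, none of them passing over all genes and 1 adjusted over the list alone (adjusted p = 0.000121). Its score ran from 5.25 to 5.84 in wild-type and from 4.25 to 5.73 in homozygous libraries. None of these list calls held with an estimated correlation (adjusted p of 0.765, 0.845, 0.901 and 0.901). The score of T cell markers spread widely between the old homozygous non-BT libraries (SD 1.44, n = 3, against 0.25 in old wild type). Without wild-type replicate 2 the fit called 4 genes and without homozygous replicate 2 it called 2, and without both it called 36.

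Averaged over the ages, 161 genes passed in non-BT cells, 27 higher and 134 lower (with quantile normalization 49 higher and 126 lower of 175). Scn3a, H2-M2, Klk1, the calcium channel gene Ryr3 and Cd8b1 had the largest falls, from -2.58 ± 0.42 for Klk1 to -1.94 ± 0.34 for Cd8b1. The largest rises in genes with values in every group were those of Gbp3 (0.80 ± 0.14), Ttc39c (0.72 ± 0.14), Snord13 (0.61 ± 0.13) and Zfp773 (0.60 ± 0.11). Of the 19S list 7 genes rose, among them Psmd2 (0.40 ± 0.06) and Psmc2 (0.43 ± 0.07), with 18 adjusted over the list alone. Of the 20S list Psma5, Psma7 and Psma1 rose, with 14 adjusted over the list alone. Of the plasmacytoid list 8 of 12 fell (12 adjusted over the list alone). Camera adjusted p for these 3 lists was 4.20e-20, 1.92e-15 and 1.56e-18, and all 3 calls were lost with an estimated correlation (adjusted p of 0.168, 0.233 and 0.168). The inflammatory genes Il1b (-1.07 ± 0.22) and Il1rn (-0.63 ± 0.10), the iron exporter gene Slc40a1 (-0.92 ± 0.17) and the transcript of Chac1 (-1.15 ± 0.21) fell. No gene passed the test of whether the genotype effect differed between old and young non-BT cells (limma, 0 calls, smallest adjusted p 0.156, with 723 genes at an unadjusted p under 0.05). The calls in young animals and their absence in old ones therefore do not show a difference by age. The plasmacytoid list was nominally higher in that contrast (median 1.30, camera adjusted p = 4.63e-14), which was lost with an estimated correlation (adjusted p = 0.669). The averaged count was 54 without old wild-type replicate 1, 507 without old wild-type replicate 2 and 401 without old homozygous replicate 2, and 12 of the 14 libraries moved it by over 1.5 times. It was 90 without the Psmb9-labelled libraries, 765 without the old animals numbered 2, 519 with array quality weights and 93 without the filter, and the interaction count was 31 without old homozygous replicate 3.

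In young B cells 9 of 12269 genes passed, 2 higher and 7 lower in homozygous animals (2 and 3 of 5 with quantile normalization). Cd163, the scavenger receptor of red pulp macrophages, fell from 10.7 ± 2.39 to 0.307 ± 0.199 FPKM (SD, n = 4 each). The complement gene C6 fell from 11.9 ± 4.83 to 0.817 ± 0.334 FPKM and Cd14, a receptor for bacterial lipopolysaccharide, from 28.9 ± 11.6 to 4.94 ± 3.29 FPKM. Stab2, a scavenger receptor of sinus endothelium, fell by 1.52 ± 0.23 and Cdh17 by -0.98 ± 0.16. Adjusted p for these 5 genes ran from 0.00288 to 0.0472. All 19 macrophage markers were negative (median -1.60), and besides Cd163 they did not pass over all genes, while 18 passed adjusted over the list alone. C1qb stood at 209.9 FPKM in wild-type and 64.7 FPKM in homozygous libraries and Slc40a1 at 190.4 and 64.1 FPKM. The macrophage score was 5.35 ± 0.09 in wild-type and 3.77 ± 0.23 in homozygous libraries (exact permutation p = 0.0286, 0.0838 after adjustment over the lists). Camera gave an adjusted p of 7.84e-26, which was lost with an estimated correlation (adjusted p = 0.177).

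**Figure D3:**
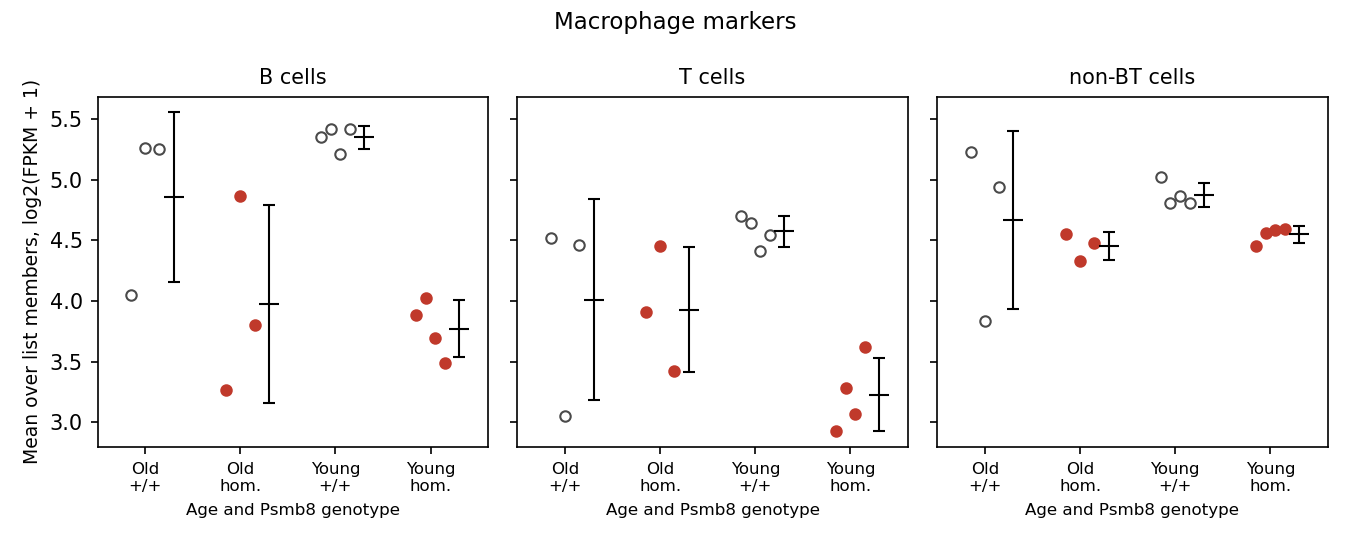
Mean log2(FPKM + 1) over the red pulp and other macrophage markers (vertical axis) in each library, by cell type, age and genotype, with open grey points for wild-type and filled red points for homozygous libraries and black bars for the mean ± SD. In young animals the wild-type and homozygous means were 5.35 and 3.77 in B cells, 4.58 and 3.23 in T cells, and 4.88 and 4.55 in non-BT cells.

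Genes of the B lineage's own later stages were also lower in young homozygous B cells as lists, without any member passing over all genes. Of the 14 plasma cell markers 10 passed adjusted over the list alone, among them Jchain (-1.41 ± 0.37) and Xbp1 (-0.78 ± 0.19). Of the 22 genes of the unfolded protein response, which antibody secretion engages, 16 did so, among them Hspa5 (-0.55 ± 0.16) and Hsp90b1 (-0.72 ± 0.20). Of 10 germinal centre markers 5 did so, and of 10 marginal zone markers 5, among them Asb2 (-1.32 ± 0.30). The 4 medians were -0.80, -0.43, -0.80 and -0.39, with camera adjusted p of 4.47e-10, 2.13e-12, 2.31e-05 and 0.000105, and all were lost with an estimated correlation (adjusted p of 0.248, 0.3004, 0.333 and 0.3004). The cell cycle list had a median of -0.62 (adjusted p = 9.18e-10, and adjusted p = 0.542 with an estimated correlation). The 20S and 19S lists were higher, with medians of 0.27 and 0.19 and 9 and 5 members adjusted over the list alone (camera adjusted p = 1.52e-10 and 1.96e-09, and adjusted p of 0.177 and 0.228 with an estimated correlation). The count of 9 genes was 2 to 5 when any 1 of the 8 young libraries was left out, 3 without the Psmb9-labelled libraries and 0 with the stricter filter. It was 113 without the old animals numbered 2, 139 with array quality weights, 180 with only the young groups fitted and 3 without the filter.

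In old B cells 1 gene passed, Gm28053 (ENSMUSG00000098715), which fell from 27.9 ± 0.965 to 12.4 ± 1.95 FPKM (SD, n = 3 each, log2 fold change -1.12 ± 0.13, limma adjusted p = 0.00806). It is a predicted gene outside the rule for names and is given because it is the only call. With the replicate number as a block, which pairs the old B cell libraries, the count was 4, and with only the old groups fitted no gene passed. Among the next smallest p, the proteasome genes Psma7 (0.59 ± 0.11), Psmb2 (0.46 ± 0.09), Psma5 (0.60 ± 0.12) and Psmc2 (0.60 ± 0.12) and the peroxiredoxin gene Prdx1 (0.72 ± 0.15) had positive fold changes, and Wdr90 (-1.14 ± 0.18, adjusted p = 0.0801), Miip, Adam23, Slc20a1 and Rpgrip1 negative ones. None of these 10 passed, and the other 9 adjusted p were 0.230. As lists, the proteasome genes were higher. All 14 genes of the 20S core were positive and 13 passed adjusted over the list alone (median 0.46, camera adjusted p = 3.16e-21, and adjusted p = 0.0477 with an estimated correlation). All 21 genes of the 19S particle were positive and 15 passed adjusted over the list alone (median 0.33, adjusted p = 4.13e-20, and adjusted p = 0.0477 with an estimated correlation). The mean log2 level of the 20S genes was 7.44 ± 0.02 in wild-type and 7.88 ± 0.13 in homozygous libraries (exact permutation p = 0.1, the smallest possible). All 30 ribosomal protein genes were positive, 28 of them past the threshold adjusted over the list alone (median 0.29, adjusted p = 4.26e-26, and adjusted p = 0.178 with an estimated correlation). All 17 heat shock genes were positive (median 0.58, adjusted p = 4.91e-08, and adjusted p = 0.465 with an estimated correlation). Type I interferon genes had a median of 0.22 (adjusted p = 7.37e-06, and adjusted p = 0.465 with an estimated correlation), with scores of 4.30 ± 0.10 and 4.53 ± 0.28 (exact permutation p = 0.400). The macrophage list had a median of -0.85 (adjusted p = 4.91e-08, and adjusted p = 0.465 with an estimated correlation). The count of 1 was 23 without homozygous replicate 2, 3 without wild-type replicate 2, 0 without either of the first replicates or wild-type replicate 3, and 18 without both animals numbered 2, whose libraries differ from the others in sex-linked genes.

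The average over ages gave the clearest view of B cells, with 85 genes passing, 27 higher and 58 lower (40 higher and 44 lower of 84 with median-of-ratios scaling). With the replicate number as a block at both ages, 216 genes passed, 36 higher and 180 lower, and 75 of the 85 were among them. Replicate numbers met the bound for pairing in old B cells only, so the block in young B cells has no such basis. Genes of the proteasome made up a good part of the rises. Of the 20S core 7 of 14 genes passed (13 adjusted over the list alone), among them Psma5 (0.48 ± 0.08), Psma7 (0.42 ± 0.07), Psmb4 (0.39 ± 0.07) and Psmb2 (0.36 ± 0.06). Of the 19S particle 6 of 21 did so (17 adjusted over the list alone), among them Psmd7 (0.57 ± 0.10), Psmd1 (0.53 ± 0.09), Psmc2 (0.52 ± 0.08) and Psmc5 (0.40 ± 0.08). The list medians were 0.36 and 0.28, with camera adjusted p of 2.31e-23 and 1.42e-22. Both calls held with an estimated correlation (adjusted p = 0.0328 for both). The 20S score was 0.34 higher over both ages (exact permutation p = 0.00143, the smallest possible, 0.0314 after adjustment over the lists). The small nucleolar RNA gene Snord13 (1.15 ± 0.21), the calcium-binding protein gene S100a6 (1.08 ± 0.18) and Prdx1 (0.58 ± 0.10) had the largest rises. The kit amplifies polyadenylated RNA, and whether the values of Snord13 stand for such RNA was not tested. Of the macrophage list 8 of 19 fell (18 adjusted over the list alone), among them Cd163 (-2.09 ± 0.28), Hpgd (-1.41 ± 0.26), Axl (-1.39 ± 0.26) and Mrc1 (-1.24 ± 0.24). The list had a camera adjusted p of 2.31e-23 that was lost with an estimated correlation (adjusted p = 0.172). C6 (-1.98 ± 0.30), Cd14 (-1.69 ± 0.31), the lipid carrier gene Apoe (-1.07 ± 0.23), the interleukin gene Il1b (-1.67 ± 0.29), Fcgr1 (-1.23 ± 0.24), Tspan15 (-1.68 ± 0.27) and Ube2e2 (-1.78 ± 0.37) fell. So did H2-Q4 of MHC class I (-0.88 ± 0.17), Asb2 of marginal zone B cells (-1.09 ± 0.23) and the T cell receptor gene Trac (-1.12 ± 0.20). Adjusted p of the genes named here ran from 0.0157 to 0.0494. No gene passed the age by genotype interaction (limma, 0 calls, smallest adjusted p 0.417, with 868 genes at an unadjusted p under 0.05). Each of the 21 lists camera called in it was lost with an estimated correlation (smallest adjusted p 0.347). The interaction count was 1 without old homozygous replicate 3, young homozygous replicate 2 or young homozygous replicate 4. The averaged count was 0 without old homozygous replicate 1, 292 without old homozygous replicate 2 and 3 to 25 without 11 of the other libraries. It was 12 without the Psmb9-labelled libraries, 235 without the old animals numbered 2, 172 with array quality weights and 13 without the filter.

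In T cells few single genes separated the genotypes. In young animals none of 13193 passed (limma, 0 calls with 1144 genes at an unadjusted p under 0.05, and 6.52% of genes without overlap where chance gives 2.86%). The smallest adjusted p was that of Klk1 (8.04 ± 0.598 FPKM in wild-type and 1.03 ± 0.962 FPKM in homozygous libraries, n = 4 each, limma adjusted p = 0.0518). S100a6 stood at 146.8 ± 30.2 and 316 ± 74.7 FPKM and Lgals1, which encodes galectin-1, at 219.99 ± 38.3 and 405 ± 93.0 FPKM. The other values were -1.87 ± 0.29 for Slc45a3, -1.12 ± 0.18 for Ddc, -0.92 ± 0.15 for Igflr1, -1.47 ± 0.26 for Ccr3, -1.51 ± 0.26 for Abcc3 and 0.87 ± 0.16 for Ms4a6c on the log2 scale, with adjusted p of 0.0624 to 0.0716. Of the 18 macrophage markers 15 passed adjusted over the list alone, among them Slc40a1 (-2.19 ± 0.41), Vcam1 (-2.16 ± 0.53) and Hmox1 (-1.49 ± 0.29), with a median of -1.44 (camera adjusted p = 1.35e-19, and adjusted p = 0.234 with an estimated correlation). All 14 plasma cell markers were negative, 4 of them past the threshold adjusted over the list alone (median -0.65, adjusted p = 3.29e-07, and adjusted p = 0.461 with an estimated correlation). Immunoglobulin genes held 7.59 ± 2.36% of summed FPKM in wild-type and 1.84 ± 0.551% in homozygous T cell libraries (exact permutation p = 0.0286). In old animals (n = 3 each) the shares were 25.9 ± 16.9% and 23.7 ± 16.0% in T cells and 22.8 ± 9.71% and 25.3 ± 17.5% in non-BT cells (exact permutation p = 0.8 for both). Replicate 2 was the highest of each of these old groups, with 44.6% and 41.9% in T cells and 33.8% and 44.2% in non-BT cells. All 14 genes of the 20S core were positive and 13 passed adjusted over the list alone (median 0.32, adjusted p = 3.83e-12, and adjusted p = 0.380 with an estimated correlation). Of the 19S genes 7 of 21 did so (median 0.22, adjusted p = 3.50e-09, and adjusted p = 0.380 with an estimated correlation). Of 21 effector and memory markers 5 passed adjusted over the list alone, among them Klrg1 (1.26 ± 0.32) and Gzmb, a granzyme of cytotoxic cells (0.79 ± 0.23), with a list median of 0.12 (adjusted p = 0.00415, and adjusted p = 0.516 with an estimated correlation). The fit called 2, 3 and 7 genes without homozygous replicates 1, 2 and 4, 80 without the old animals numbered 2, 58 with array quality weights and 97 with only the young groups fitted.

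In old T cells none of 13193 genes passed (limma, 0 calls with 502 genes at an unadjusted p under 0.05 and 7.70% without overlap, where chance gives 10%), and this count stayed 0 without any 1 of the 6 libraries. Genes with the smallest p included Ddc, the decarboxylase of dopamine and serotonin synthesis (12.2 ± 0.806 FPKM in wild-type and 5.79 ± 1.25 FPKM in homozygous libraries, n = 3 each), the 20S gene Psma1 (0.52 ± 0.12 on the log2 scale), Prdx1 (0.58 ± 0.14), Ppa1 (0.46 ± 0.11), Gzmb (1.06 ± 0.26), Pdk2 (-0.67 ± 0.17) and Mylip (-0.61 ± 0.16), all with a limma adjusted p of 1. The 16 genes of glycolysis were higher as a list (median 0.22, camera adjusted p = 6.00e-07), and this held with an estimated correlation (adjusted p = 0.00688), although no member passed even adjusted over the list alone. The 20S and 19S lists had medians of 0.25 and 0.26 (adjusted p = 2.22e-11 for both, and adjusted p = 0.291 for both with an estimated correlation). Of 48 type I interferon genes 35 were positive (median 0.18, adjusted p = 0.000163, and adjusted p = 0.563 with an estimated correlation). Averaged over the ages, 1 gene passed, Ddc, which fell by 1.05 ± 0.14 (adjusted p = 0.0364). The glycolysis list had a median of 0.14 in that average and was called both ways (adjusted p = 7.56e-05, and adjusted p = 0.0358 with an estimated correlation). The 20S and 19S lists had medians of 0.27 and 0.24 with 12 and 14 members past the threshold adjusted over the list alone (adjusted p = 3.39e-17 and 5.34e-15), lost with an estimated correlation (adjusted p of 0.215 and 0.152). The 20S score was 0.29 higher over both ages (exact permutation p = 0.00286, 0.0321 after adjustment). No gene passed the interaction in T cells (limma, 0 calls with 511 genes at an unadjusted p under 0.05), although leaving out young homozygous replicate 2 or 4 gave 1. The averaged count was 0 without 8 of the libraries left out singly, 8 without old wild-type replicate 2, 27 without old homozygous replicate 2, 2 without young wild-type replicate 2, 8 without young homozygous replicate 4 and 66 without both old animals numbered 2. It was 0 without the Psmb9-labelled libraries, 61 with array quality weights, and 7 with quantile normalization, 4 of them higher and 3 lower.

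Wild-type animals of the age groups were compared with each other. The age groups follow the ranges of library numbers in part, and 1 of the 3 old wild-type animals, number 2, differed from all other wild-type animals in sex-linked genes, so the comparison does not isolate age. In T cells 30 of 13193 genes passed, 27 higher and 3 lower in old animals, and 10 of them were immunoglobulin genes. Gzmm, a granzyme, rose from 10.2 ± 3.98 FPKM (n = 4) to 47.7 ± 23.96 FPKM (n = 3), the chemokine receptor gene Cxcr3 from 78.3 ± 6.09 to 153.8 ± 8.32 FPKM, and S100a6 from 146.8 ± 30.2 to 311 ± 39.4 FPKM. Asns, which makes asparagine, rose from 2.93 ± 0.510 to 19.8 ± 14.1 FPKM, Prg2 of eosinophils by 2.24 ± 0.39 on the log2 scale and the ubiquitin ligase gene Rnf128 by 1.74 ± 0.31. Trat1, a T cell receptor adaptor, fell from 71.2 ± 2.08 to 31.9 ± 7.27 FPKM. Of the 21 effector and memory markers 2 rose (11 adjusted over the list alone, with Gzma the 1 that was lower) and the list was higher (median 0.48, camera adjusted p = 7.38e-10). All 13 naive T cell markers were negative (median -0.55, adjusted p = 7.79e-08). Both were lost with an estimated correlation (adjusted p of 0.429 and 0.449). Plasma cell markers were higher too (median 1.17, adjusted p = 1.87e-09, and adjusted p = 0.449 with an estimated correlation). The immunoglobulin share was 7.59 ± 2.36% in young and 25.9 ± 16.9% in old T cell libraries (exact permutation p = 0.0286). Old replicates 1, 2 and 3 held 11.6%, 44.6% and 21.6%, so replicate 2 raised the old mean. With the library range as a covariate, which leaves the age comparison to the range that holds both ages, no gene passed, and none passed without the filter. In each cell type the range that holds both ages has old replicate 3 and young replicates 1 and 2 of the wild type. Few libraries thus carry that comparison, and the absence of calls does not tell an effect of the range from a lack of power. The count of 30 genes was 147 without old replicate 1, 1 without old replicate 2, 0 without old replicate 3, and 7, 1, 0 and 7 without young replicates 1, 2, 3 and 4. It was 186 with array quality weights, 12 without the old animal numbered 2 and its homozygous counterpart, 11 with only the groups compared and 7 without the Psmb9-labelled libraries.

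In wild-type non-BT cells 27 of 13587 genes passed with age, 12 higher and 15 lower, and 8 were immunoglobulin genes. Genes of natural killer cells fell. Gzma fell from 989 ± 168 FPKM (n = 4) to 296 ± 93.2 FPKM (n = 3), Nkg7 from 1249.9 ± 165 to 524 ± 108 FPKM and the receptor gene Klra7 from 57.2 ± 4.25 to 19.5 ± 6.90 FPKM, and Gzmb and Klrc2 fell by 1.40 ± 0.20 and 1.87 ± 0.33. Of 14 markers of these cells 3 passed over all genes and all 14 adjusted over the list alone (median -1.60, camera adjusted p = 1.09e-16, and adjusted p = 0.385 with an estimated correlation). Jchain rose from 687 ± 267 to 2536 ± 1033 FPKM, Ighm by 2.43 ± 0.32, Asns by 1.62 ± 0.27 and Gp2 by 1.58 ± 0.26, and Ppm1j fell by 1.89 ± 0.31. Crygn (3.42 ± 2.27 FPKM in young libraries) was listed at 0 FPKM in old ones and Rny3 (30.1 ± 9.49 FPKM in old libraries) at 0 FPKM in young ones. All 32 cell cycle genes were positive, 26 of them past the threshold adjusted over the list alone (median 0.80, adjusted p = 2.01e-18, and adjusted p = 0.683 with an estimated correlation). All 20 erythroid markers were positive too, 4 of them past it (median 1.20, adjusted p = 1.04e-10, and adjusted p = 0.738 with an estimated correlation). In B cells no gene passed with age (limma, 0 calls with 768 genes at an unadjusted p under 0.05, and 1 call without old replicate 1). In non-BT cells no gene passed with the library range as a covariate or without the filter, 20 did without the Psmb9-labelled libraries, 9 without the old animals numbered 2 and 68 with array quality weights. Without old replicates 2 and 3 the count was 4 and 55, and without young replicates 1, 2 and 3 it was 0, 0 and 1.

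Whether the genotype effect, averaged over the ages, differed between cell types was tested over all 42 libraries. Between non-BT and B cells 84 of 15143 genes differed, 37 with a higher and 47 with a lower effect in non-BT cells. The lower ones included Ryr3 (difference of log2 fold changes -1.98 ± 0.28), Scn3a, H2-M2 (-1.87 ± 0.35), Ly6d (-1.66 ± 0.30) and Atp2a1 (-1.61 ± 0.32). The higher ones included macrophage and monocyte genes that had lower values in homozygous B cells, namely Adamdec1 (2.28 ± 0.50), the Fc receptor gene Fcgr1 (1.93 ± 0.33), Adgre4 (1.71 ± 0.40) and Csf1r, the receptor for macrophage growth factor (1.66 ± 0.37). Unequal carry-over of macrophages or their RNA into the B cell libraries was not excluded as a source of such differences. Between T and non-BT cells 54 genes differed, 48 higher and 6 lower in T cells (40 and 12 of 52 with quantile normalization). They included Ryr3 (2.05 ± 0.28), H2-M2 (2.04 ± 0.35), Scn3a, Pdlim4 (1.90 ± 0.39) and Nudt17 (1.86 ± 0.40) among the higher and Atp8a2 (-1.09 ± 0.25), Zfp683 (-1.04 ± 0.24) and Dram2 (-0.47 ± 0.10) among the lower. Between T and B cells 20 genes differed, 18 higher and 2 lower in T cells (5 and 2 of 7 with quantile normalization), among them Serpine2 (1.95 ± 0.35), Pdlim4 (1.89 ± 0.39), Fcer1g (1.75 ± 0.38), the lysozyme gene Lyz2 (1.62 ± 0.33), Hfe (1.55 ± 0.33), Ifit1bl1 (-1.22 ± 0.23) and Zfp53 (-0.75 ± 0.14). The plasmacytoid list differed between non-BT and B cells by a median of -0.86 (cameraPR adjusted p = 3.00e-15) and between T and non-BT cells by 1.07 (adjusted p = 6.23e-15), and the macrophage list between non-BT and B cells by 1.08 (adjusted p = 8.89e-16). With an estimated correlation on differences within animals these calls were lost (adjusted p of 0.135, 0.182 and 0.517). Of the plasmacytoid list, Runx2, Klk1, Smim5, Cd300c, Ccr9, Cox6a2 and Siglech stood at 0.314 to 1.07 FPKM in young wild-type B cells. These genes had little room to fall there, so their difference from non-BT cells follows in part from their low level. The other members stood at 10.9 (Pacsin1) to 3860 FPKM (Ly6d). The 84 and 54 were 288 and 226, and the 20 was 98, without the old animals numbered 2, and 37, 18 and 6 without the Psmb9-labelled libraries. Leaving out 1 library gave 49 (old homozygous B replicate 3) to 180 (old homozygous B replicate 2) in place of 84, 13 (old wild-type non-BT replicate 1) to 145 (old wild-type non-BT replicate 2) in place of 54. For the 20 genes it gave 5 (old homozygous T replicate 3) to 101 (old homozygous B replicate 2). Of the 42 libraries 9, 10 and 22 moved the counts of 84, 54 and 20 by over 1.5 times. The count of 54 was lower with a pseudocount of 0.1, the stricter filter or the replicate block, and higher with a pseudocount of 5.

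Genes near Psmb8 were examined because a segment of chromosome 17 carried along with the variant would give linked differences. Within 10 Mb of Psmb8, 8 of 346 tested genes passed in young non-BT cells, against 221 of 13240 elsewhere (two-sided Fisher's exact p = 0.391). The 8 all fell and included 5 other genes of the MHC region besides H2-M2, namely H2-Oa (34092340 to 34095234), H2-Ob (34238903 to 34254414), H2-Eb2 (34325665 to 34341412), H2-Q4 (35379617 to 35385290) and H2-Q10 (35470089 to 35474563), and further Pacsin1 (27655509 to 27711482) and Cyp4f37 (32621309 to 32636184). Averaged over the ages the counts were 7 of 346 in non-BT cells (Fisher's exact p = 0.133) and 3 of 319 in B cells, which were Pla2g7, H2-Q4 and Wdr90 (Fisher's exact p = 0.487). In non-BT cells the narrower window of 5 Mb gave 6 genes or 2.99% for the average, against 1.16% elsewhere (Fisher's exact p = 0.0325), and 7 genes or 3.48% for young animals, against 1.66% (Fisher's exact p = 0.0860). The wider window of 20 Mb gave 9 of 487 genes for both (Fisher's exact p = 0.193 and 0.719). In B cells, averaged over the ages, 5 Mb gave 1 of 187 genes and 20 Mb 4 of 446 (Fisher's exact p = 1 and 0.553). Fisher's exact test takes genes as independent, while the MHC genes among the calls all fell together. The p of the windows were not adjusted, so the value for the average at 5 Mb does not show a linked segment.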

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

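The tests of the 3 patterns weighed first were planned after the patterns were seen, apart from the comparison of proteasome genes with lists of like expression, whose prediction was written before its result. Plasmacytoid dendritic cell markers in young non-BT cells had a score 1.84 lower in homozygous libraries. A growing share of another cell type would lower every remaining type alike. Scores of natural killer cells, neutrophils, basophils, erythroid cells, megakaryocytes and progenitors were set against this, and the largest fall among these 6 was -0.336 (megakaryocytes), which counts against dilution as the source of the whole fall. Scores outside these 6 fell by more, though unequally (CD8 T cells -1.30, plasma cells -0.973, B cells -0.652 and conventional dendritic cells -0.562), and that of monocytes rose by 0.392. B cells carried into the wild-type libraries would account for a median of 0.0132% of a marker's level and for at most 6.93%, which counts against them as the source. A lower share of plasmacytoid cells among the non-BT cells or lower expression within them could each give the pattern, and these data do not separate the 2.

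Macrophage markers had scores 1.58 lower in young homozygous B cells and 1.35 lower in T cells. The score differed by -0.326 in non-BT cells, where members with a high level there moved little (Apoe by 0.032 from 1304.6 FPKM) and others fell (Slc40a1 by -1.16, Vcam1 by -1.08). Expression by other cells would hide a fall of the former. The 11 members that were tested in non-BT cells and lower in young wild-type non-BT than B libraries had a median of -0.565 and a lower quartile of -0.783 there, so an equal fall of macrophage RNA in all 3 preparations was not excluded. It, unequal carry-over of macrophages or their RNA, and lower expression within B and T cells stay open. That 16 of 18 members lay below -0.5 in both B and T cells restates the pattern and does not decide among them. Of the 18 members 13 were higher in young wild-type B than non-BT libraries (Vcam1 at 139.6 and 17.8 FPKM). The genotype as cause of any of these was not tested.

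The 20S and 19S proteasome genes had positive list medians in homozygous libraries of all 3 cell types at both ages. With an estimated correlation the list calls held in old B cells and for the average in B cells, and were lost in young B cells (adjusted p of 0.177 and 0.228) and in T and non-BT cells (0.215 and 0.152, and 0.233 and 0.168, for the averages). Scaling between libraries does not account for it, since the lowest list median under the 2 other scalings was 0.211. A rise of all genes at a like expression level does not either, since the combined list stood at percentile 100 among 10000 random lists matched for expression in every comparison. A response of proteasome genes to the variant could give this pattern, and no other measurement here tests it.

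Other splits of the libraries into the same group sizes were fitted after the counts were known. In young non-BT cells 1 of 35 splits, the real one, gave as many genes (229, highest other 1), a share under 1 in 20. The share was under 1 in 20 in young B cells too (1 of 35 splits, 9 genes, highest other 2). So it was for age in T cells (1 of 35, 30 genes, highest other 4) and non-BT cells (1 of 35, 27 genes, highest other 1). For the averages over ages the share was under 1 in 20 in B cells (1 of 100, 85 genes, highest other 26) and non-BT cells (1 of 100, 161 genes, highest other 43). For the differences between cell types it was so too (T minus B 1 of 100, 20 genes, highest other 8, non-BT minus B 1 of 100, 84 genes, highest other 62, and T minus non-BT 2 of 100, 54 genes, highest other 54). For T minus non-BT another split thus called as many genes as the real one. The shares were not adjusted over the comparisons. The share was not under 1 in 20 for young T cells (35 of 35, 0 genes, highest other 1), age in B cells (35 of 35, 0 genes, highest other 1) or the average in T cells (28 of 100, 1 gene, highest other 46). Where the real split called 0 genes, every split gives as many, so the share was fixed and decides nothing. The same applies to the interactions and to old T and non-BT cells below. For the interactions, with 0 genes, 100 of 100 splits gave as many, and the highest others were 66 in B, 10 in T and 283 in non-BT cells. The splits with 10 and 283 kept the young libraries parted by genotype, so their calls hold the young genotype effect. The same holds for the splits with 26 and 46 for the averages and for the other split with 54. The split with 66 mixed the genotypes at both ages, which points to a structure of the samples other than genotype. In old animals the 10 splits are too few for a share under 0.05. There 5 of 10 splits gave as many as the 1 real gene in B cells (highest other 175), 10 of 10 as many as the 0 in T cells (highest other 24) and 10 of 10 as many as the 0 in non-BT cells (highest other 138). Each of these highest splits put both animals numbered 2 on one side, which points to a structure of the samples. Both animals differ from all others in sex-linked genes, and no fit held a term for sex. In B cells, where the numbers pair the libraries, 4 splits, the real one included, part all 3 pairs, and the highest of the others among them called 0 genes. The splits that called 1 or more besides the real one left pairs together on one side. Of the other splits that part all 3 replicate numbers, the highest called 3 genes in T cells and 6 in non-BT cells, against 0 for the real split in both.

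A single library stood apart from the other 3 of its group in 11 of 300 groups tested, by a ratio of gap to range above Dixon's 95% critical value, where chance gives about 1 in 20 groups. Among scores these were plasmacytoid markers in young wild-type B cells (replicate 2, ratio 0.907, 5.47 against 5.36 to 5.37), conventional dendritic cell markers there (replicate 4, 0.853), natural killer markers in young homozygous B cells (replicate 1, 0.982, 0.857 against 1.63 to 1.65), CD8 T cell markers in young wild-type non-BT cells (replicate 1, 0.844) and exhausted T cell markers in young homozygous non-BT cells (replicate 4, 0.831). Among genes they were Stab2 in young homozygous B cells (replicate 4, 0.837, 0.525 against 0.990 to 1.08 FPKM), Lgals1 in young homozygous T cells (replicate 4, 0.869, 544 against 350.2 to 376 FPKM) and Pomp in young wild-type non-BT cells (replicate 1, 0.866). In young homozygous non-BT cells replicate 4 stood apart for Scn3a (0.900, 1.23 against 0.139 to 0.248 FPKM), Spib (0.859) and Il7r (0.866).

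The genotype effect, averaged over ages, differed between cell types for genes named within a cell type or near Psmb8, by a limma test of the difference of log2 fold changes. Between T and B cells this was Asb2 (1.24, adjusted p = 0.0441). Between non-BT and B cells the lower effects in non-BT cells were those of S100a6 (-0.87, adjusted p = 0.0479), H2-M2 (-1.87), Cd200 (-1.37), Ccr9 (-1.56), Ly6d (-1.66), Ccr7 (-1.29), Supt3 (-0.92), H2-Ob (-0.61), Cd8b1 (-1.53), Scn3a (-2.1954, adjusted p = 1.25e-07), Ryr3 (-1.98), Bglap3 (-1.04), Pacsin1 (-1.40) and Cyp4f37 (-1.21). Ccr9 stood at 0.449 FPKM in young wild-type B cells, where it had little room to fall. The higher effects in non-BT cells were those of Fcgr1 (1.93, adjusted p = 0.00241), Asb2 (1.11), Slc45a3 (1.20), Tspan15 (1.41) and Cd14 (1.61). For macrophage and monocyte genes among them, unequal carry-over into the B cell libraries was not excluded. Between T and non-BT cells the effects were higher in T cells for Spib (1.11), H2-M2 (2.035), Ly6d (1.38), Ccr7 (1.19), Irf8 (0.64), Cd8b1 (1.5042), Scn3a (1.9993, adjusted p = 1.31e-06), Ryr3 (2.05), Bglap3 (0.82), Cyp4f37 (1.25) and H2-Q10 (1.13). List scores that moved in opposite ways in every library were those of interferon-gamma-inducible genes (-0.262 in young B and 0.40015 in old non-BT cells), monocyte markers (-0.427 in young B and 0.392 in young non-BT cells) and effector and memory T cell markers (-0.340 in young B and 0.216 in young T cells), and these differences between single comparisons were not tested. Averaged over the ages, cameraPR called a higher effect for these lists, in non-BT than B cells for the first (adjusted p = 0.0368) and for monocyte markers (adjusted p = 0.00314), and in T than B cells for the last (adjusted p = 0.00270). With an estimated correlation these calls were lost (adjusted p of 0.836, 0.815 and 0.195).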

How the results depend on the processing

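Library depth, 9480000 to 25730000 estimated fragments, limits the genes at low FPKM. Of 147 called gene values, none reversed under any alternative. They stayed past the threshold in 141 cases with median-of-ratios scaling, 138 with a pseudocount of 5, 135 with quantile normalization, 132 with one of 0.1, 106 with the library range as covariate, 61 without the Psmb9-labelled libraries and 54 without the filter. With the replicate block 93 of 125 stayed, and with each library left out in turn 699 of 1550 values stayed and 851 did not. Of 211 list calls 6 held with an estimated correlation and 36 with a rotation test, and 1639 of 1892 list values stayed with each library left out in turn. Leaving out the old animals numbered 2 was chosen after seeing the data, and 131 of the 147 stayed. The block had no fit for age, and fitting only the groups compared had none for averages, interactions and cell type differences. Replicate numbers met the bound of 0.1 for pairing in old B cells only. By title the same animals gave the old T and non-BT libraries, so a pairing there is not excluded. The lowest correlation of same-numbered deviations was 0.0951 in old T cells (6 of 6 libraries closest to their own number) and 0.0374 in old non-BT cells (5 of 6), and in young animals 3, 5 and 6 of 8 libraries of B, T and non-BT cells were closest to their own. In old B cells the replicate block moved the count to 4 and changed no list call. Of the counts below, the cause of a change was not tested.

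With the replicate block the count was 151 in young B cells, 216 for the average in B cells, 8 in young T cells, 6 for the average in T cells, 1 for the interaction in non-BT cells and 17 for T minus non-BT. A pseudocount of 0.1 gave 2 in young B, 1 in old non-BT and 16 for age in non-BT cells, and 34, 43 and 8 for T minus B, non-BT minus B and T minus non-BT. A pseudocount of 5 gave 15 in young B, 1 in young T, 2 for the average in T, 1 in old non-BT and 51 for age in non-BT cells, and 167 for non-BT minus B and 129 for T minus non-BT. Without the filter the counts were 3 in old B, 3 in young B, 13 for the average and 1 for the interaction in B cells, 1 in old T, 1 for the interaction and 0 for age in T cells, and 4 in old, 104 in young, 93 for the average, 2 for the interaction and 0 for age in non-BT cells. The stricter filter gave 0 in young B and 56 for the average in B cells, and 34, 45 and 12 for T minus B, non-BT minus B and T minus non-BT. Quantile normalization gave 5 in young B, 11 in young T, 7 for the average in T cells and 7 for T minus B, and median-of-ratios scaling 13 for T minus B.

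With the library range as covariate the counts were 2 in old B, 46 for the average in B, and 0 for age in T and in non-BT cells. There the median log2 fold changes of lists whose direction with age turned, in the median or in the test, were -0.068 for MHC class I and -0.192 for immediate early genes in B cells, 0.0339 for NF-kB and 0.00952 for immediate early genes in T cells, and -0.216 for immediate early genes in non-BT cells. Fitting only the groups compared gave 0 in old B, 180.0 in young B, 97 in young T, 11 for age in T, 1 in old, 705 in young and 16 for age in non-BT cells. Array quality weights gave 139 in young B, 172 for the average in B, 58 in young T, 61 for the average and 186 for age in T, and 756 in young, 519 for the average, 1 for the interaction and 68 for age in non-BT cells, with 58, 241 and 155 for T minus B, non-BT minus B and T minus non-BT.

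Without the Psmb9-labelled libraries the counts were 3 in young B, 12 for the average in B, 0 for the average in T, 7 for age in T, and 1 in old, 68 in young and 90 for the average in non-BT cells, with 6, 37 and 18 for the cell type differences in the same order. Without the old animals numbered 2 they were 18 in old, 113 in young and 235 for the average in B cells, 1 in old, 80 in young, 66 for the average and 12 for age in T cells, 36 in old, 635 in young, 765 for the average, 1 for the interaction and 9 for age in non-BT cells, and 98, 288 and 226 for the cell type differences. Medians of lists that turned were -0.155 for cell cycle and 0.130 for erythroid genes with age in T cells and -0.00122 for immunoproteasome genes in old non-BT cells.

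Leaving out 1 library at a time gave 0 to 23 in old B, 2 to 5 in young B, 0 to 292 for the average, 0 to 1 for the interaction and 0 to 1 for age in B cells. In T cells it gave 0 to 0 in old, 0 to 7 in young, 0 to 27 for the average, 0 to 1 for the interaction and 0 to 147 for age. In non-BT cells it gave 0 to 4 in old, 60 to 137 in young, 54 to 507 for the average, 0 to 31 for the interaction and 0 to 55 for age. For T minus B it gave 5 to 101, for non-BT minus B 49 to 180.0 and for T minus non-BT 13 to 145. Medians of lists that turned ran from -0.129 (without homozygous replicate 2) to 0.742 for cell cycle genes in old B cells. With age in T cells they ran from -0.155 to 0.418 for cell cycle and from 0.184 to 1.6996 for erythroid genes (lowest without wild-type replicate 2). In old non-BT cells they ran from -0.364 to 0.0594 for MHC class II and from -0.289 to 0.0298 for NF-kB genes (highest without wild-type replicate 1).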

Other observations

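Further gene groups moved with age in wild-type T cell libraries. All 22 genes of the unfolded protein response were positive (median 0.59, camera adjusted p = 7.38e-10), as were 17 of 20 immediate early genes (median 0.85, adjusted p = 5.17e-09) and 10 of 11 regulatory T cell markers (median 0.64, adjusted p = 0.000208). Plasma cell markers (median 1.17) and the immunoglobulin share (7.59% to 25.9%, with old replicate 2 at 44.6%) were higher in the same libraries. Which cells carried the unfolded protein response was not tested. In wild-type B cells age-associated B cell markers were higher in old animals as a list (median 0.46, adjusted p = 0.00148), while none of their 15 members passed. With an estimated correlation these calls were lost (adjusted p of 0.449, 0.449, 0.476 and 0.711). With the library range as covariate the median of the immediate early genes in T cells was 0.00952 (adjusted p = 0.915), and the calls of regulatory T cell markers (median 0.208, adjusted p = 0.142) and of age-associated B cell markers (median 0.0594, adjusted p = 0.707) were lost too. Few libraries carry the age comparison under that covariate, so these lost calls do not tell an effect of the range from a lack of power. Without old wild-type replicate 2 the median of the age-associated B cell markers was 0.0254 (adjusted p = 0.756).

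The old animals numbered 2 of both genotypes differed from all others in sex-linked genes. Ddx3y of the Y chromosome stood at or below 0.113 FPKM in their 6 libraries and at 23.2 to 49.9 FPKM in the other 36, and Xist, expressed from the inactive X chromosome, at 2.66 to 6.38 FPKM against at most 0.219 FPKM. Such values mark females among males, though the labels do not state the sex. No fit held a term for sex. The libraries of the old homozygous animal numbered 2 also held single immunoglobulin genes at a level not seen elsewhere, with Ighv5-9 at 20085 to 65311 FPKM against at most 346 FPKM and Ighg1 at 19109 to 73147 FPKM against at most 3680 FPKM.

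Hypotheses of this re-analysis were tested with lists written after the data had been seen, with each prediction written before its list was tested. The first was that dendritic cells expressing Ccr7 and Fscn1 were lower in young homozygous non-BT cells. A list of 18 genes of such mature cells, which includes genes already called here, had a median log2 fold change of -0.915 with 17 of 18 negative (camera p = 4.19e-12, p = 0.00778 with an estimated correlation, and exact permutation p = 0.0286 for its score). This is in line with the hypothesis but not independent of it. In old animals the median was -0.506 (p = 0.0221 with an estimated correlation, and exact permutation p = 0.2). The next was that the rise of proteasome genes extends to their assembly factors and partners in all 3 cell types. The list of 15 measured genes had median log2 fold changes, averaged over ages, of 0.110 in B cells (p = 0.0229 with an estimated correlation), 0.121 in T cells (p = 0.0226) and 0.0313 in non-BT cells (p = 0.204), so the predicted rise in all 3 was not met.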
